A study of Mus musculus with 3530 samples.

How the data were processed

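The samples are 3530 single cells of the mouse medial prefrontal cortex, each a GEO sample of its own. The labels give for each cell a condition and a mouse number (m1 to m5), and the titles give a plate and, in sets 2 to 4, a sorting gate. Replicates are animals, 20 in all and 5 per condition, and a second Context-Only mouse numbered 5 was kept apart as 5b. The labels give no schedule of training, tamoxifen or recall, and they do not say what a shared mouse number marks.

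The deposited table holds counts per gene and cell, read counts by the authors' own processing, with 23355 genes including the reporter, which was left out of all library sizes and tests (23354 genes remained). The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm10, without saying which values rest on which build. The tool that assigned reads to genes is not given in the sources used here. The values were checked to be whole numbers, and no 2 cells were identical. GENCODE vM21 (GRCm38) served only for gene types and positions, and 22347 symbols (95.7%) of the table were found in it. The table does not rest on that annotation, so a position is that of the gene of the same symbol.

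Every cell held at least 100000 reads, up to 6840943 (median 813104), and between 527 and 10839 genes. The filter of 500 genes and 10000 counts removed 0 cells. Cells were sorted into plates singly, so no doublet caller was run. Counts were scaled per cell, logged and clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden 1.0 through leidenalg 0.10.2), under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Clusters were named by marker lists fixed at the start, as excitatory or inhibitory, whichever list had the higher mean. No other name could be given. Median genes per cell were 7270 in excitatory and 5506 in inhibitory neurons. The 2 clusters of fewest genes per cell (284 cells, 8.05%) are called low-gene clusters.

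Raw counts were summed per animal, and per gate or class where the comparison called for it, where 10 or more cells were present. The pos comparisons used 8 sums (Fear-Recall 3, Fear-Only 2, Context-Only 3) of 112 to 329 cells and 141604815 to 277685602 counts. Sums of pos excitatory neurons held 77 to 214 cells and those of pos inhibitory neurons 32 to 126 cells. The all-gate comparisons used 19 sums of 17 to 521 cells and 17831821 to 463123041 counts. The gate comparison used 16 sums of 8 animals (Context-Only 2, 3 and 4, Fear-Only 2 and 3, Fear-Recall 2 and 3, Homecage 2) of 55 to 329 cells and 34330142 to 277685602 counts. The all-gate sums of different animals mix gates in different parts.

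Sums were tested with edgeR 4.0.16 (TMM scaling, quasi-likelihood test, filterByExpr with a minimum count of 10 and a minimum total of 15) under R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The gate comparison had the animal as a block, and the interaction compared the gate difference of Fear-Recall with that of the other conditions. Gene lists, 22 of pathways and 13 of markers with 658 genes in all, of which 39 were missing from the table, were fixed before the data were examined, along with the comparisons, the rule for named genes and the alternatives listed first below. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Fry served as a further look at the immediate early list. Scores are means of log2(CPM + 1) over a list. CPM of named genes carries TMM scaling and is given as mean ± SD over animals. Fold changes against a group at 0 are taken against a floor of 3 counts over the group. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only, and comparisons of shares and scores used exact permutations or sign flips of animals.

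Named genes were chosen by a fixed rule. Among genes past an adjusted p of 0.05 with a mean log2 CPM of at least 5, the 12 largest rises and the 12 largest falls were eligible, and where fewer than 6 passed in a direction, all that passed. Where none passed in a comparison, the 4 of smallest p per direction were eligible and are said not to have passed. From each list described, 2 to 4 members of smallest p were added. Predicted genes were counted and not named. Of the genes the rule made eligible, 2 are not reported here.

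In simulated counts with the spread of each design, 200 genes were changed, 100 by 2-fold and 100 by 4-fold. The changed genes had a mean log2 CPM of at least 5. Counts were drawn independently, without effects of set or animal, so recovery and false calls may differ in the real sums. In the pos comparison (20381 genes tested) edgeR recovered 1% and 60% with 7 false calls of 68, and DESeq2 19% and 89% with 81 false of 189. In the all-gate comparison (19698 genes) edgeR recovered 27% and 92% with 3 false of 122, and DESeq2 48% and 94% with 75 false of 217. In the gate comparison (17752 genes) edgeR recovered 86% and 100% with 6 false of 192, and DESeq2 94% and 100% with 126 false of 320.

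Whether the mouse number pairs animals across conditions was checked from correlations of the log2 CPM deviations of the sums from their condition means, over genes of a mean CPM of 10 or more. Same-number pairs of Fear-Recall and Context-Only had r of 0.645, 0.513 and 0.731 in pos neurons, 0.568, 0.446 and 0.692 in pos excitatory and 0.480, 0.359 and 0.499 in pos inhibitory neurons. Over all gates the 28 same-number pairs lay between 0.147 and 0.667, and the 107 other pairs between −0.592 and 0.441, 24 of them over 0.1. The number was therefore read as pairing these comparisons, and its block is given as an alternative for the gene lists. Counts of genes that passed with this block are not reported here. The main fits, fixed before, hold condition only, so their tests and counts leave the pairing out. In pos neurons Fear-Only shares only 2 numbers with either other condition (r of 0.420 and 0.095 with Fear-Recall, 0.457 and 0.192 with Context-Only), too few to decide. Over all gates its same-number pairs had r of 0.418 to 0.632 with Fear-Recall and 0.296 to 0.647 with Context-Only (5 pairs each), so the number was read as pairing these animals too. It was first read as a number only, and that reading changed after both fits had been seen.

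Alternative settings were DESeq2 1.42.0, no filter on low counts, limma-trend on the mean of per-cell CPM with a pseudocount of 1, 20 or more cells per sum, a cell filter of 1000 genes, the set number as a block, cells of no given gate added to pos cells, no animal block, Leiden resolutions of 0.5 and 2, an estimated correlation, and leaving out each animal. Alternatives chosen after the data were seen were to leave out the low-gene clusters, to test genes of a mean CPM of 10 or more, to fit each neuron class of the gate comparison, and to thin each cell to 100000 reads. Leaving out each animal was planned for the fits but not for the shares of cells. Homecage animal 1 and the pos gate of Fear-Only animal 4 held 1 cell each and gave no sum. The plate marked with both gates was used in all-gate sums only. The 5 planned comparisons of astrocytes, microglia, endothelial cells, oligodendrocyte precursors and oligodendrocytes were not run. Clusters were named only as excitatory or inhibitory neurons, so no cells carried these names.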

Results

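Messenger RNA was measured in 3530 single cells of the mouse medial prefrontal cortex, prepared by Smart-seq2, a plate-based method that amplifies full-length transcripts of individually sorted cells. The animals carried TRAP2, an activity-dependent recombinase that works only while tamoxifen is present, and Ai14, a tdTomato reporter that the recombinase switches on, so that cells active during labelling stay marked. The labels give 4 conditions of a contextual fear experiment, which are Fear-Recall (1342 cells), Context-Only (912 cells), Fear-Only (841 cells) and Homecage (435 cells). Each condition holds 5 animals, identified by a set number from 1 to 5 that is shared across conditions, and set 5 of Context-Only holds a second animal (5b) in place of a set 1 animal. Sample titles name a sorting gate, pos or neg, in sets 2 to 4, which gave 1806 pos and 779 neg cells. One plate of Homecage animal 3 (96 cells) is marked with both gates, and the 849 cells of sets 1 and 5 carry no gate name. Every cell held at least 100000 reads, with a median of 813104, and the median number of genes detected was 6719.

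The pos gate was enriched for the reporter transcript. Among the 8 animals with both gates, 68.3% ± 26.5 (SD, n = 8) of pos cells and 9.63% ± 2.01 of neg cells held at least 1 reporter read. The difference of 58.6 percentage points was positive in 8 of 8 animals (exact two-sided sign-flip test, p = 0.0078, the smallest this design allows). Pos cells differed widely between animals, from 23.5% (95% interval 15 to 34.0) in Homecage animal 2 and 34.5% (26.8 to 42.8) in Context-Only animal 2 to 96.9% (94.4 to 98.5) in Fear-Recall animal 3. With every cell thinned to 100000 reads the shares were 54.0% and 4.72%, and the difference was positive in 7 of 8 animals (exact p = 0.0156). In the remaining one, Homecage animal 2, the thinned share was 5.88% in both gates. In the neg gate of Homecage animal 4, 0 of 17 cells held a reporter read, which allows a share of up to 17.6% at a floor of 3 counts (exact 95% interval up to 19.5).

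**Figure D1:**
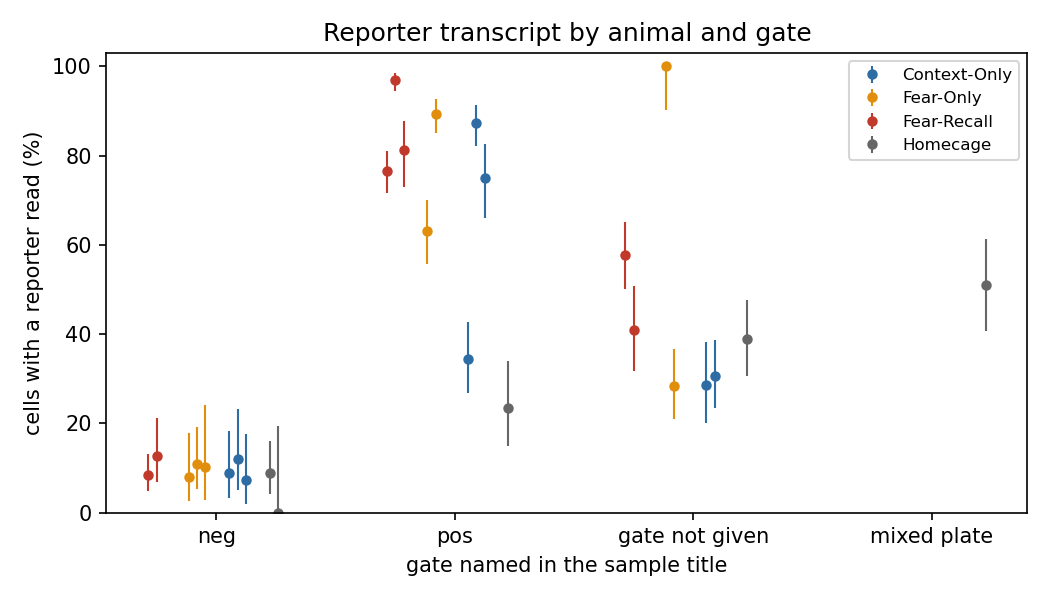
Share of cells with at least 1 reporter read (percent, vertical axis) by sorting gate (horizontal axis), with each point an animal coloured by condition and each bar the exact 95% binomial interval; animals with a single cell in a gate are left out. The neg cells lie at or below 12.8%, and the pos cells between 23.5% and 96.9%.

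The cells formed 20 clusters, 12 excitatory-neuron-like (2317 cells) and 8 inhibitory-neuron-like (1213 cells, 34.4%), called excitatory and inhibitory neurons from here on. Leading genes of the inhibitory clusters included Vip, Penk and Calb2, which mark an interneuron class of the cortex, Sst and Cort, Pvalb and Cox6a2, Ndnf and Reln, and Sncg and Cnr1. The excitatory clusters were led by genes such as Cux2 and Rorb, Rprm and Foxp2, Wfs1 and Calb1, Nnat and Oprk1, and Pou3f1 and Pdyn. Some excitatory clusters held cells mostly of certain sets, such as the one led by Cux2 and Rorb, with only 2 cells in each of sets 1, 4 and 5. The naming chose between these 2 classes only, so no cluster could be named for glial or vascular cells. At a Leiden resolution of 2 a cluster of 12 cells, named excitatory, was led by astrocyte genes such as Apoe, Mlc1, Slc1a3 and Gja1. Its mean of astrocyte markers (1.031) was above that of excitatory markers (0.827). The pos gate held more inhibitory neurons than the neg gate of the same animals, 40.8% ± 6.10 against 21.7% ± 3.73 (SD, n = 8). The difference of 19.1 percentage points was seen in 8 of 8 animals (exact two-sided sign-flip test, p = 0.0078). Within the pos gate, inhibitory neurons made up 33.3% ± 5.53 of Fear-Recall cells and 39.5% ± 7.25 of Context-Only cells (n = 3 each). This difference did not pass an exact two-sided permutation test (p = 0.30, where the smallest possible is 0.10). The share was lower in Fear-Recall in 3 of 3 sets, at 38.3% against 44.8%, 34.2% against 42.5% and 27.4% against 31.2%, which was not tested by pairs.

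The first comparison set pos against neg neurons of the same animals, which asks how the reporter-sorted cells differ from their neighbours. Pos and neg cells lay on separate plates in all of these animals but Context-Only animal 4. In the others an effect of the gate thus cannot be told apart from one of the plate. Genes of inhibitory neurons rose in the pos sums. Vip, a neuropeptide of an interneuron class, was at 7843 ± 2175 CPM in pos and 2484 ± 1497 in neg neurons (SD, n = 8 animals; log2 fold change 1.80, SE 0.25). Tac2, which encodes neurokinin B, was at 1301 ± 864 against 301 ± 223.7 CPM (2.25, SE 0.32). Neuropeptide Y, Npy, was at 805 ± 524 against 208 ± 153.5 CPM (2.08, SE 0.27). On the log2 scale, the prepronociceptin gene Pnoc rose by 1.45 (SE 0.16) and the growth factor Igf1 by 1.44 (SE 0.21). The parathyroid-hormone-like hormone Pthlh rose by 1.49 (SE 0.25), and the interneuron transcription factors Prox1 and Dlx1 by 1.31 (SE 0.18) and 1.04 (SE 0.14). The tetraspanin Cd63 (1.67, SE 0.19), the long noncoding RNA Mir670hg (1.52, SE 0.23), Adarb2 (1.42, SE 0.21) and Pcp4l1 (1.33, SE 0.09; 264.2 ± 64.7 against 105 ± 23.2 CPM) rose as well. Each of these genes was higher in pos neurons in 8 of 8 animals. Within excitatory neurons alone 5 of them turned direction, Npy (−0.93, SE 0.63), Igf1 (−2.31, SE 1.44), Pthlh (−0.44, SE 1.71), Cd63 (−0.59, SE 0.52) and Adarb2 (−1.57, SE 1.3), none past the test there.

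Only 5 genes fell in pos neurons. The cell adhesion gene Amigo2 fell by 1.57 (SE 0.21) from 21.7 ± 10.8 to 7.55 ± 4.66 CPM. The homeobox gene Meis2 fell by 0.79 (SE 0.12) from 51.2 ± 8.77 to 29.4 ± 3.36 CPM, and the LIM-domain gene Lmo3 by 0.75 (SE 0.13). Pid1 fell by 0.70 (SE 0.12), and the neuronal pentraxin Nptx1 by 0.62 (SE 0.10) from 246 ± 59.2 to 158.8 ± 31.5 CPM. All 5 were lower in pos neurons in 8 of 8 animals on CPM with TMM scaling. Within inhibitory neurons alone Meis2 turned to 4.30 (SE 2.64, adjusted p = 0.720). In GRCm38 (mm10) coordinates of GENCODE vM21, Vip lies on chromosome 10 from 5639218 to 5647617, Tac2 on chromosome 10 from 127724478 to 127731768, Npy on chromosome 6 from 49822710 to 49829507, Igf1 on chromosome 10 from 87858265 to 87937042. Pcp4l1 lies on chromosome 1 from 171173262 to 171196268. Amigo2 lies on chromosome 15 from 97244125 to 97247287, Meis2 on chromosome 2 from 115863064 to 116065839, Lmo3 on chromosome 6 from 138362918 to 138581968 and Nptx1 on chromosome 11 from 119538719 to 119547753, all protein-coding.

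**Figure D2:**
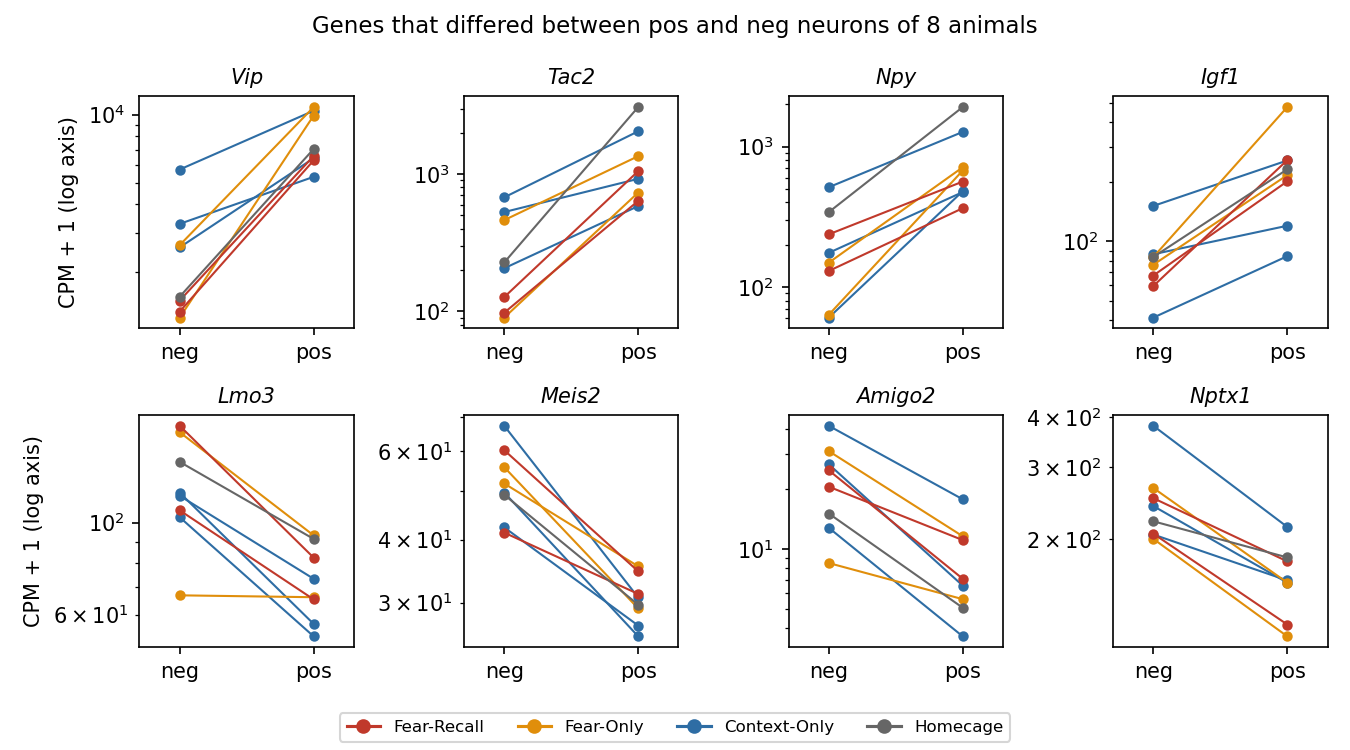
CPM + 1 with TMM scaling (log axis) of 8 genes in the neg and pos neurons of 8 animals, with each line an animal coloured by condition. Vip, Tac2, Npy and Igf1 are higher and Lmo3, Meis2, Amigo2 and Nptx1 lower in pos neurons, with the line of Fear-Only animal 2 nearly level for Lmo3.

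Of 17752 genes tested, 51 passed an adjusted p of 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, animal as a block), 46 higher and 5 lower in pos neurons. The smallest adjusted p was 0.00018 (Pcp4l1). It was 0.0173 for Vip, Npy, Prox1, Dlx1 and Amigo2, 0.0218 for Tac2, and 0.0142 for Cd63 and Pnoc. It was 0.0261 for Igf1 and Adarb2, 0.0265 for Mir670hg, and 0.0457 for Pthlh, and among falling genes 0.0242 for Meis2, 0.0456 for Lmo3, 0.0467 for Pid1 and 0.0312 for Nptx1. DESeq2 passed 647 genes, 50 of them shared, and limma-trend 90, 44 of them shared. Without the animal block 21 genes passed, all among the 51, and without the 2 clusters of fewest genes per cell 28 passed, 22 of them shared. The count rested on most of the animals: it was 1 without Fear-Recall animal 2, 5 without Fear-Recall 3, 6 without Fear-Only 3 and 26 without Fear-Only 2. It was 27 without Context-Only 3, 30 without Context-Only 4, 31 without Homecage 2 and 32 without Context-Only 2. Pcp4l1 passed with each animal left out, while every other gene named above was at an adjusted p of 0.0555 to 0.139 without Fear-Recall animal 2. Vip was also at 0.0505 without Fear-Only animal 2, 0.0706 without Fear-Only animal 3 and 0.0663 without Fear-Recall animal 3, and Tac2, Npy, Prox1, Amigo2 and Dlx1 fell short without either of the latter 2 animals. Without the animal block Tac2 (0.0777), Npy (0.102), Pnoc (0.0572), Igf1 (0.118), Prox1 (0.0788), Amigo2 (0.223), Nptx1 (0.232), Pthlh, Lmo3 and Pid1 did not pass. Without the low-gene clusters Tac2 (0.0609), Pthlh (0.136), Igf1 (0.111), Prox1 (0.275), Adarb2 (0.0779), Dlx1 (0.0722) and Pid1 did not pass.

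Immediate early genes, which neurons transcribe within minutes of activity, were higher in pos neurons as a group. The list had a median log2 fold change of 0.50 with 25 of 30 members above 0. Its camera test gave an adjusted p of 1.8e-08 (adjusted p = 0.0748 with an estimated correlation). Members that passed over all genes were 2, the secretogranin Scg2 (0.995, SE 0.14, adjusted p = 0.0173; 835 against 415 CPM) and the AP-1 subunit Fosl2 (1.38, SE 0.22, adjusted p = 0.0320), and 12 passed adjusted over the list alone. Egr1 had a log2 fold change of 0.54 (SE 0.10, adjusted p = 0.0741). The mean score of the list was 0.30 higher in pos neurons (log2(CPM + 1), SD 0.24) in 8 of 8 animals (exact two-sided sign-flip test, p = 0.0078). With each cell weighing the same the score difference was 0.27 and positive in 6 of 8 animals (exact p = 0.0469).

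Markers of inhibitory neurons had a median of 1.08 with 10 of 12 above 0, 5 of them past the test over all genes and 9 adjusted over the list alone (adjusted p = 4.7e-13; adjusted p = 0.00532 with an estimated correlation). This was the only list of 29 still past the threshold with an estimated correlation. Markers of excitatory neurons had a median of −0.42 with 7 of 8 below 0 (adjusted p = 0.000142; adjusted p = 0.0748 with an estimated correlation). None passed over all genes and 3 passed adjusted over the list alone. The vesicular glutamate transporter Slc17a7 (59.98 against 85.7 CPM, log2 fold change −0.57, SE 0.14) and Neurod2 (−0.63, SE 0.14) had adjusted p-values of 0.179 and 0.129. Deep-layer excitatory genes had a median of −0.35 with 7 of 10 below 0 and 3 past the test adjusted over the list alone (adjusted p = 0.00107; adjusted p = 0.181 with an estimated correlation), with Bcl11b at −0.65 (SE 0.17) and Fezf2 at −0.37 (SE 0.11), or 0.02 within excitatory neurons alone. Within excitatory neurons alone the adjusted p was 0.900 for the inhibitory, 0.844 for the excitatory and 0.357 for the deep-layer list. The inhibitory and excitatory lists also named the neuron classes, so their values are not independent of the class shares.

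Ribosomal protein genes were higher in pos neurons, with a median of 0.33 and 82 of 84 above 0 (adjusted p = 2.3e-19; adjusted p = 0.414 with an estimated correlation). Genes of oxidative phosphorylation were too, with a median of 0.32 and 69 of 75 above 0 (adjusted p = 9.6e-11; adjusted p = 0.507 with an estimated correlation). Rps3 had a log2 fold change of 0.33 (SE 0.12, adjusted p = 0.382) and Ndufa13 of 0.46 (SE 0.19, adjusted p = 0.426), while the complex I gene Ndufs1 went the other way at −0.48 (SE 0.14, adjusted p = 0.256). The mean score of the ribosomal list was above 0 in 6 of 8 animals (mean 0.22, SD 0.36; exact p = 0.133). Proteasome genes had a median of 0.14 (adjusted p = 0.00102; adjusted p = 0.414 with an estimated correlation), a call lost with per-cell means (adjusted p = 0.0888). Astrocyte markers, with a median of 0.45 and 10 of 10 above 0 (adjusted p = 0.0035; adjusted p = 0.250 with an estimated correlation), stood at low levels, such as Gja1 at 2.36 against 1.10 CPM, and were not past the threshold over genes of a mean CPM of 10 or more (adjusted p = 0.259). No gene of these 4 lists passed over all genes. Genes encoded by the mitochondrion had a median of 0.14 with 11 of 13 above 0 (adjusted p = 0.0179; adjusted p = 0.507 with an estimated correlation), which turned to −0.01 with per-cell means (adjusted p = 0.394). Genes of glutamate receptors and the postsynaptic density had a median of −0.10 with 25 of 35 below 0 (adjusted p = 0.0266; adjusted p = 0.250 with an estimated correlation), with Gria3 at −0.45 (SE 0.11), and astrocyte transport genes of 0.25 (adjusted p = 0.0447; adjusted p = 0.338 with an estimated correlation). The receptor call was lost without Context-Only animal 2 (adjusted p = 0.0803) and Fear-Only animal 3 (0.0507), and that of the transport genes without Fear-Only animal 3 (0.0517), Fear-Recall animal 2 (0.0665) or 3 (0.142) and Homecage animal 2 (0.0833). The mitochondrial call was lost without Homecage animal 2 (0.106). The other 18 lists did not pass (smallest adjusted p 0.0709).

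**Figure D3:**
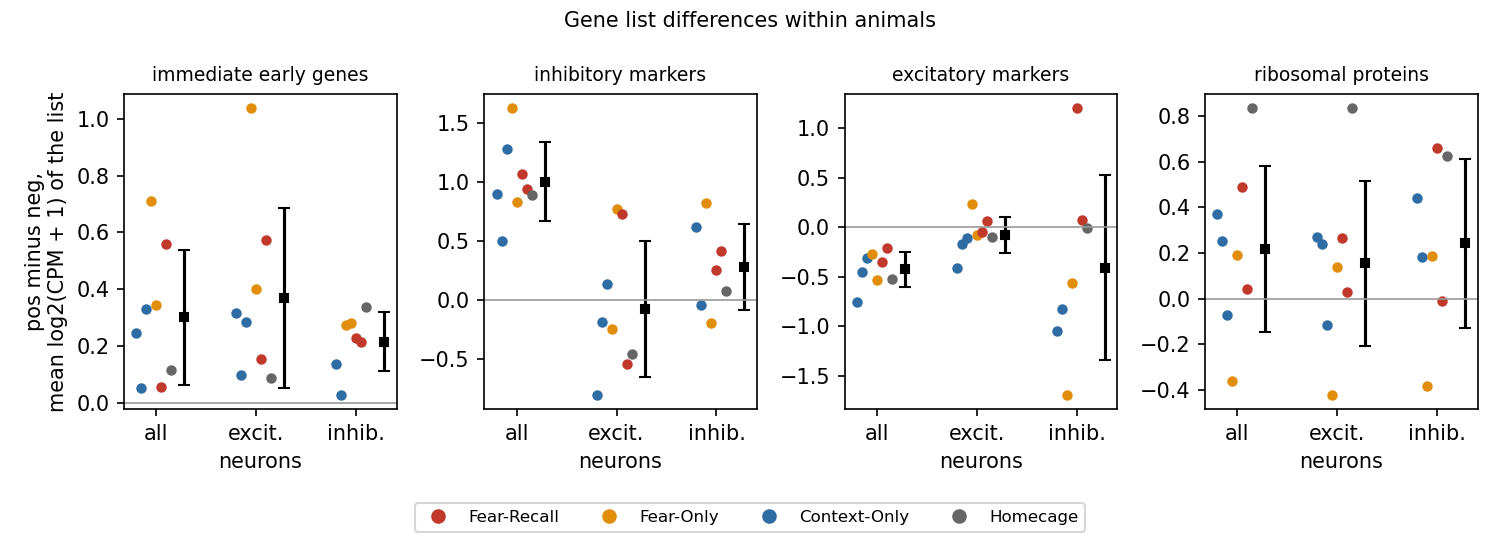
Difference of the mean log2(CPM + 1) of 4 gene lists between pos and neg neurons (vertical axis) over all neurons and within each class (horizontal axis), with each point an animal, and black squares and bars the mean and SD over animals. The immediate early list lies above 0 in 8 of 8 animals for all and for excitatory neurons, and in 7 of 7 for inhibitory neurons.

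Comparisons within a class were added after the data were seen. Within excitatory neurons, pos cells of the 8 animals held more Cdkn1a, an inhibitor of cyclin-dependent kinases, at 340 ± 137.8 against 145.6 ± 38.3 CPM (log2 fold change 1.16, SE 0.13). The medium neurofilament gene Nefm rose by 0.94 (SE 0.11; 161 against 84.3 CPM). The immediate early transcription factor Egr1 rose by 0.70 (SE 0.09; 728 ± 127.4 against 448 ± 65.7 CPM). Nxph1, a secreted neurexin ligand, fell by 2.56 (SE 0.26) to 4.88 from 25.5 CPM. It was among the leading genes of the inhibitory cluster led by Sst. Trp53i11 fell by 1.36 (SE 0.18) to 40.2 from 101 CPM. These 5 were among the 6 genes that passed of 16779 (edgeR, adjusted p = 0.0235 for Cdkn1a and Nefm, 0.0358 for Trp53i11, 0.0354 for Egr1 and 0.0170 for Nxph1), and none of the 6 was among the 51 above. Immediate early genes had a median of 0.51 with 24 of 29 above 0, 1 past the test over all genes and 15 adjusted over the list alone (adjusted p = 6.5e-14; adjusted p = 0.160 with an estimated correlation). Nr4a1 stood at 0.85 (SE 0.13, adjusted p = 0.145) and Nr4a2 at 1.53 (SE 0.31, adjusted p = 0.234). The list score was higher in 8 of 8 animals (mean 0.37, SD 0.32; exact two-sided sign-flip test, p = 0.0078). Ribosomal protein genes had a median of 0.26 with 82 of 84 above 0 (adjusted p = 3.0e-15; adjusted p = 0.700 with an estimated correlation). Egr1 lies on chromosome 18 from 34859823 to 34864984, Cdkn1a on chromosome 17 from 29090976 to 29100727 and Nxph1 on chromosome 6 from 8948431 to 9249032.

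Within inhibitory neurons, with 7 animals, no gene of 14377 passed in edgeR (smallest adjusted p 0.468), 1111 genes had an unadjusted p under 0.05, and no other tool was run. The median log2 fold change of all genes was 0.20. Genes of smallest p included Lamp5, at 54.6 ± 41.6 in pos and 255 ± 162 CPM in neg neurons (log2 fold change −2.27, SE 0.41), and the GABA receptor subunit Gabra5 at 11.8 against 51.1 CPM (−2.21, SE 0.43). Others were Mpped1 at 23.3 against 68.4 CPM (−1.58, SE 0.23), Gucy1a3, a subunit of soluble guanylate cyclase, at 84.5 against 28.1 CPM (1.64, SE 0.30) and Cthrc1 at 61.7 against 21.8 CPM (1.62, SE 0.29). Vip stood at 19710 ± 4809 against 11120 ± 6168 CPM (0.97, SE 0.25, adjusted p = 0.591) and Cck at 2011 against 931 CPM (1.32, SE 0.30, adjusted p = 0.563). The immediate early list had a median of 0.52 with 20 of 28 above 0 and 1 past the test adjusted over the list alone (adjusted p = 0.0260; adjusted p = 0.272 with an estimated correlation). Its score was higher in 7 of 7 animals (mean 0.22, SD 0.10; exact two-sided sign-flip test, p = 0.0156). Scores of other cell types were higher as well, each in 6 of 7 animals, by 0.52 for mural (p = 0.0469), 0.46 for microglia (0.0469), 0.30 for oligodendrocyte precursor (0.0312) and 0.53 for astrocyte markers (0.0938), without adjustment over lists. Genes of GABA receptors and synapses had a median of −0.09 and a mean of −0.29, with 3 lower adjusted over the list alone (adjusted p = 0.0135; adjusted p = 0.272 with an estimated correlation). Excitatory markers, with 5 genes tested, had a median of −1.17 (adjusted p = 0.0135; adjusted p = 0.272 with an estimated correlation), and ribosomal protein genes of 0.38 with 82 of 84 above 0 (adjusted p = 4.3e-17; adjusted p = 0.402 with an estimated correlation).

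Whether the gate difference itself differed between Fear-Recall and the other conditions was tested as an interaction over the same 16 sums. No gene of 17752 passed in edgeR (smallest adjusted p 0.9999), 116 had an unadjusted p under 0.05, DESeq2 passed 2 and limma-trend 0. The genes of smallest p were Zfp94 (difference of log2 fold changes 1.52, SE 0.40) and the aquaporin Aqp5 (3.29, SE 0.94) on the higher side, and Igdcc3 (−7.30) and the adrenomedullin gene Adm (−10.02), both under 4 CPM on average, on the lower side. The immediate early list had a median of −0.04 (adjusted p = 0.426). Deep-layer excitatory genes had a median of −0.52 with 9 of 10 below 0 and none past the test, over all genes or adjusted over the list alone (adjusted p = 0.0363; adjusted p = 0.617 with an estimated correlation). Sulf1 stood at −1.02 (SE 0.50) and Fezf2 at −0.40 (SE 0.24). That call was lost without Context-Only animal 2 (adjusted p = 0.0661), 3 (0.0787) or 4 (0.116), without Fear-Recall animal 2 (0.147), without the low-gene clusters (0.133) and without the animal block (0.0756). Without Fear-Recall animal 2 or 3 that arm holds 1 animal, assumed to vary like the other conditions.

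The comparison of Fear-Recall with Context-Only in pos neurons asks what marks reporter-sorted cells after recall of a fear memory. No gene passed in edgeR, so the following are values. Of the genes named in this paragraph DESeq2, which made 81 false calls in simulated counts against 7 by edgeR, passed Pcna-ps2 (adjusted p = 3.7e-07), Sstr5 (1.6e-05), Epha7 (0.000881), Ddc (0.0207) and Zdhhc15 (0.0371). The activity-regulated gene Arc was at 413 ± 242.9 CPM in Fear-Recall and 165.9 ± 33.1 in Context-Only (SD, n = 3 each; log2 fold change 1.32, SE 0.41), and the phosphatase genes Dusp6 and Dusp1 had log2 fold changes of 1.22 (SE 0.50) and 0.87 (SE 0.37). The ephrin receptor Epha7 was at 77.2 ± 3.98 against 34.4 ± 4.14 CPM (1.17, SE 0.22). On the lower side were Rab3b, a vesicle-associated GTPase, at 226.8 ± 75.8 against 541 ± 114.6 CPM (−1.25, SE 0.34), and Pcbd1 at 21.7 ± 3.66 against 50.9 ± 19.6 CPM (−1.23, SE 0.32). Lower too were Zdhhc15 (−2.58, SE 0.68) and Ddc, the aromatic amino acid decarboxylase, at 0.288 against 2.67 CPM (−3.22, SE 0.85). The somatostatin receptor gene Sstr5 held 590 counts in Fear-Recall and 0 in Context-Only, at least 150.7-fold higher against a floor of 3 counts over the group. This was a low level in sums of 160856708 to 277693460 counts per Fear-Recall animal, reporter included. With cells of no given gate added, its change in Fear-Only against Context-Only turned to −0.13, so Context-Only cells were not all at 0. Pcna-ps2, a pseudogene whose reads may be shared with Pcna, stood at 11.01 ± 2.84 against 1.55 ± 0.472 CPM (2.82, SE 0.45). Arc lies on chromosome 15 from 74669083 to 74672570, Epha7 on chromosome 4 from 28813131 to 28967499, Rab3b on chromosome 4 from 108879063 to 108943324 and Sstr5 on chromosome 17 from 25489875 to 25497288.

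As groups, ribosomal protein genes were lower in Fear-Recall, with a median of −0.62 and 84 of 85 below 0 (camera, adjusted p = 5.0e-13; adjusted p = 0.650 with an estimated correlation). Lower as well were genes of oxidative phosphorylation, with a median of −0.69 and 72 of 75 below 0 (adjusted p = 1.7e-11; adjusted p = 0.648 with an estimated correlation) and of the proteasome, with a median of −0.39 and 29 of 31 below 0 (adjusted p = 4.6e-07; adjusted p = 0.648 with an estimated correlation). Rpsa was at 312 ± 49.4 against 461 ± 137.8 CPM (−0.56, SE 0.28) and Psmc5 at −0.47 (SE 0.25), while Ndufs1 went the other way (0.84, SE 0.34). Both the ribosomal and the oxidative phosphorylation list turned direction without Context-Only animal 2, to medians of 0.08 and 0.15 (adjusted p = 0.972 each). In that animal 57.9% of pos cells belonged to the 2 clusters of fewest genes per cell. Within sets 2, 3 and 4 the ribosomal score differed by −0.56, −0.19 and −0.13 between Fear-Recall and Context-Only (mean −0.29, SD 0.24). The score of oxidative phosphorylation differed by −0.60, −0.11 and −0.16 (mean −0.29, SD 0.27), and that of the proteasome by −0.17, −0.11 and −0.22 (mean −0.16, SD 0.06).

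Immediate early genes had a median of 0.26 with 22 of 30 above 0 (adjusted p = 0.00883; adjusted p = 0.648 with an estimated correlation). Their score differed by 0.24, 0.26 and 0.88 within sets 2, 3 and 4. Their call was lost without Context-Only animal 4 (adjusted p = 0.510), Fear-Recall animal 3 (0.0887) or Fear-Recall animal 4 (0.1999), and with cells of no given gate added (0.838). Genes of other cell types moved with the condition at low levels. Oligodendrocyte markers had a median of −1.64 with 10 of 10 below 0 and 3 past the test adjusted over the list alone (adjusted p = 7.1e-05; adjusted p = 0.567 with an estimated correlation), such as Mobp at 7.84 ± 0.903 against 24.6 ± 10 CPM (−1.65, SE 0.45). Microglia markers had a median of 4.17 with 9 of 11 above 0 and 5 past the test adjusted over the list alone (adjusted p = 0.000152; adjusted p = 0.567 with an estimated correlation). Homeostatic microglia genes had a median of 1.46 with 13 of 15 above 0 and 4 past the test adjusted over the list alone (adjusted p = 0.000152; adjusted p = 0.282 with an estimated correlation), with Csf1r at 2.56 ± 3.47 against 0.0108 CPM and Tmem119 at 1.98 ± 2.15 against 0.00184 CPM, both past the threshold in DESeq2 (adjusted p = 1.6e-05 and 0.000474). With cells of no given gate the adjusted p of these lists was 0.0576 and 0.107, and over genes of a mean CPM of 10 or more that of the homeostatic list was 0.554. Deep-layer excitatory genes had a median of −0.19 with 9 of 10 below 0 (adjusted p = 0.0240; adjusted p = 0.648 with an estimated correlation), with Foxp2 at 12.4 against 23.3 CPM. That call was lost with the set as a block (adjusted p = 0.141), with per-cell means (0.285), without the low-gene clusters (0.193), over genes of a mean CPM of 10 or more (0.344), without Context-Only animal 3 (0.0811) or 4 (0.510) or Fear-Recall animal 2 (0.588), and turned to a median of 0.12 with cells of no given gate (0.838).

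**Figure D4:**
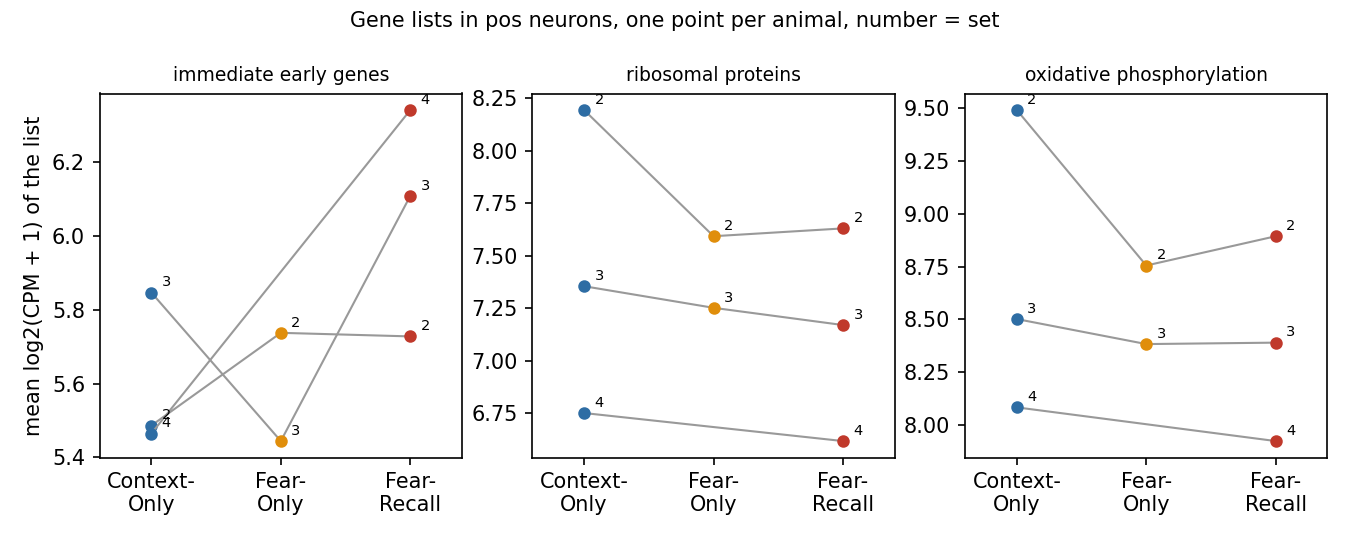
Mean log2(CPM + 1) of 3 gene lists in pos neurons (vertical axis) by condition (horizontal axis), with each point an animal and lines joining animals of the same set number. Homecage is not shown. Of the 8 animals shown Context-Only animal 2 has the highest ribosomal score (8.19), and in each of sets 2, 3 and 4 Fear-Recall lies below Context-Only for ribosomal genes and above it for immediate early genes.

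Over all 20381 genes, 0 passed in edgeR (smallest adjusted p 0.970) and 688 had an unadjusted p under 0.05, with 1019 expected by chance. The fit and that expectation leave out the pairing by set. In 3 other splits of these animals that also parted every same-number pair, at most 432 genes were under 0.05. So few splits allow no share under 0.05, so these counts cannot decide on chance. DESeq2 passed 24 genes and limma-trend 0. In simulated counts of this design, drawn without set effects, edgeR recovered 1% of genes changed 2-fold and 60% of those changed 4-fold. The changed genes had a mean log2 CPM of at least 5. Most 2-fold changes would thus be missed by this fit under those settings. Beside the 8 lists described, 23 did not pass (smallest adjusted p 0.147), the inhibitory markers (median −0.15, adjusted p = 0.246) and the excitatory markers (median 0.21, adjusted p = 0.218) among them. The score of the excitatory markers was higher in Fear-Recall within sets 2, 3 and 4, by 0.67, 0.22 and 0.35 (mean 0.41, SD 0.23).

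Within pos excitatory neurons, Rab3b was at 94.5 ± 47.4 CPM in Fear-Recall and 273 ± 16.96 in Context-Only (log2 fold change −1.53, SE 0.35, n = 3 each), and the myelin gene Mobp at 8.65 ± 0.370 against 30.9 ± 13.98 CPM (−1.84, SE 0.39). Gt(ROSA)26Sor, an antisense-type transcript at the locus that hosts the Ai14 reporter, was at 7.38 against 24.3 CPM (−1.72, SE 0.40), and Pcna-ps2 at a log2 fold change of 2.64 (SE 0.47). Of 19292 genes 0 passed in edgeR (smallest adjusted p 0.922), 772 had an unadjusted p under 0.05, limma-trend passed 0 and DESeq2 27, these 4 genes among them. Ribosomal protein genes had a median of −0.63 with 84 of 85 below 0 (adjusted p = 7.6e-16; adjusted p = 0.639 with an estimated correlation). Proteasome genes had a median of −0.42 (adjusted p = 4.1e-08; adjusted p = 0.584 with an estimated correlation). Oligodendrocyte markers had a median of −2.15 with 2 past the test adjusted over the list alone (adjusted p = 3.9e-05; adjusted p = 0.410 with an estimated correlation). The immediate early list did not pass (median 0.22, adjusted p = 0.174). Without Context-Only animal 2 the ribosomal median was 0.00 (adjusted p = 0.295). Genes of oxidative phosphorylation had a median of −0.73 with 72 of 75 below 0 (adjusted p = 2.0e-14; adjusted p = 0.584 with an estimated correlation), which turned to 0.04 without that animal (adjusted p = 0.288). Microglia markers had a median of 5.72 and 6 past the test adjusted over the list alone (adjusted p = 0.0022; adjusted p = 0.584 with an estimated correlation), lost without Context-Only animal 4 (adjusted p = 0.156). Homeostatic microglia genes had a median of 2.94, or 3.36 with genes at 0 set to their bound, and 1 past the test adjusted over the list alone (adjusted p = 0.00269; adjusted p = 0.410 with an estimated correlation), lost without Context-Only animal 4 (adjusted p = 0.0996). Deep-layer genes had a median of −0.28 (adjusted p = 0.00496; adjusted p = 0.584 with an estimated correlation), lost without Context-Only animal 3 (adjusted p = 0.0688) or 4 (0.363) or Fear-Recall animal 2 (0.256).

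Within pos inhibitory neurons, the AP-1 gene Junb was at 328 ± 118.9 CPM in Fear-Recall and 141.3 ± 36.6 in Context-Only (log2 fold change 1.21, SE 0.37, n = 3 each). Dusp1 was at 487 ± 295 against 175.5 ± 68.1 CPM (1.47, SE 0.47). The carboxylase gene Ggcx was at 23.7 ± 3.21 against 5.20 ± 1.5 CPM (2.18, SE 0.49) and the activin receptor Acvr1 at 31.7 against 5.76 CPM (2.46, SE 0.55). The mitochondrial import gene Timm22 was at 49.5 against 135 CPM (−1.44, SE 0.38). Ptgis, the prostacyclin synthase gene, held 340 counts against 0, at least 93.7-fold higher. This was a low level in Fear-Recall sums of 37176852 to 111986611 counts, reporter included. Of 17646 genes 0 passed in edgeR (smallest adjusted p 0.997), 726 had an unadjusted p under 0.05, limma-trend passed 0 and DESeq2 38, Ptgis, Ggcx and Acvr1 among them. Immediate early genes had a median of 0.34 with 23 of 29 above 0 (adjusted p = 0.00279; adjusted p = 0.827 with an estimated correlation), lost without Context-Only animal 4 (adjusted p = 0.112). Ribosomal protein genes had a median of −0.56 with 83 of 84 below 0 (adjusted p = 4.2e-08; adjusted p = 0.866 with an estimated correlation), which turned to 0.26 without Context-Only animal 2 (adjusted p = 0.165). Without the same animal the call of oxidative phosphorylation (median −0.65 with 71 of 75 below 0, adjusted p = 8.0e-07; adjusted p = 0.866 with an estimated correlation) turned to a median of 0.36 (adjusted p = 0.0841), and that of the proteasome (median −0.46, adjusted p = 0.000174; adjusted p = 0.827 with an estimated correlation) was lost (adjusted p = 0.452). Homeostatic microglia genes had a median of 3.31, or 2.05 with genes at 0 set to their bound (adjusted p = 0.0171; adjusted p = 0.827 with an estimated correlation), and microglia markers of 5.26, or 4.88 (adjusted p = 0.0274; adjusted p = 0.827 with an estimated correlation). The former was lost without Context-Only animal 2 (adjusted p = 0.235) or 4 (0.0686) or Fear-Recall animal 3 (0.137), and the latter without Context-Only animal 2 (0.221) or 3 (0.292) or Fear-Recall animal 2 (0.0738) or 3 (0.429).

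Fear-Recall against Fear-Only in pos neurons compared 3 with 2 animals. The share of pos cells with a reporter read was higher in Fear-Recall in sets 2 and 3, so the same limit holds for condition here. Arc was at 413 ± 242.9 against 122.6 ± 0.369 CPM (log2 fold change 1.75, SE 0.49). The neuronal transcription factor Npas4 was at 48.99 ± 30.7 against 13.3 ± 3.02 CPM (1.88, SE 0.62). Hddc3 was at 16.3 ± 6.21 against 83.97 ± 2.23 CPM (−2.36, SE 0.38) and the imprinted gene Nnat at 93.6 ± 10.04 against 217.2 ± 40.6 CPM (−1.21, SE 0.27). Aldh1l1 was at 10.2 against 1.89 CPM (2.44, SE 0.52). Eno1b, a processed copy of Eno1 whose reads may be shared with it, was at 92.8 ± 9.11 against 0.153 ± 0.0394 CPM (9.26, SE 2.26). None of 20381 genes passed in edgeR (smallest adjusted p 0.9999), 384 had an unadjusted p under 0.05, limma-trend passed 0 and DESeq2 7, Eno1b, Hddc3, Aldh1l1 and Nnat among them. Without Context-Only animal 2, which shares the estimate of spread, 2 genes passed, Eno1b among them (adjusted p = 0.00012).

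Here immediate early genes had a median of 0.32 with 23 of 30 above 0 (adjusted p = 0.000439; adjusted p = 0.620 with an estimated correlation), lost without Fear-Only animal 3 (adjusted p = 0.292) and with cells of no given gate (0.0926). Their score differed by −0.01 within set 2 and by 0.67 within set 3. Synaptic vesicle genes had a median of 0.21 with 38 of 50 above 0 (adjusted p = 0.0115; adjusted p = 0.620 with an estimated correlation), including Syn1 (0.68, SE 0.30) and Sv2b (1.03, SE 0.45) but not Rab3b (−1.02, SE 0.37). This call was lost without Fear-Recall animal 4 (adjusted p = 0.183), with cells of no given gate (0.183) and over genes of a mean CPM of 10 or more (0.0518). Ribosomal protein genes were lower, with a median of −0.30 and 85 of 85 below 0 (adjusted p = 7.3e-06; adjusted p = 0.722 with an estimated correlation), lost without Fear-Only animal 2 (adjusted p = 0.378) or Fear-Recall animal 4 (0.232) and with the set as a block (0.365). Their score differed by 0.04 and −0.08 within sets 2 and 3. Genes of oxidative phosphorylation had a median of −0.20 with 73 of 75 below 0 (adjusted p = 0.00644; adjusted p = 0.739 with an estimated correlation), which turned to 0.07 without Fear-Only animal 2 (adjusted p = 0.882) and 0.04 without Fear-Recall animal 4 (0.742). With the set as a block it turned to 0.09 (adjusted p = 0.575), and within sets 2 and 3 the score differed by 0.14 and 0.01. Without Fear-Only animal 2 or 3 that arm holds 1 animal, assumed to vary like the other groups. No member of these lists passed over all genes or adjusted over the list alone.

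Fear-Only against Context-Only in pos neurons compared 2 with 3 animals. Hddc3 was at 83.97 ± 2.23 against 22.8 ± 7.36 CPM (log2 fold change 1.88, SE 0.38) and Eno1b at 0.153 against 84.6 ± 75.4 CPM (−9.12, SE 2.25). Sstr5 held 177 counts in Fear-Only and 0 in Context-Only, at least 84.7-fold higher. The Notch ligand gene Dll4 held 114 counts against 0, at least 54.5-fold higher. With cells of no given gate added to pos cells both turned direction, Sstr5 to −0.13 and Dll4 to −1.75. Homeostatic microglia genes had a median of 2.50 with 14 of 15 above 0 and 5 past the test adjusted over the list alone (adjusted p = 3.4e-08; adjusted p = 0.0607 with an estimated correlation), such as Selplg at 2.03 ± 0.195 against 0.0364 CPM. Siglech held 349 counts against 0. Over genes of a mean CPM of 10 or more the list was at an adjusted p of 0.235. Microglia markers had a median of 3.79 with 4 past the test adjusted over the list alone (adjusted p = 5.4e-07; adjusted p = 0.343 with an estimated correlation). Synaptic vesicle genes had a median of −0.21 but a mean of 0.00 (adjusted p = 0.00488; adjusted p = 0.460 with an estimated correlation), lost without Context-Only animal 4 (adjusted p = 0.268) and with the set as a block (0.222). Proteasome genes had a median of −0.23 (adjusted p = 0.0149; adjusted p = 0.833 with an estimated correlation), lost without Context-Only animal 2 (adjusted p = 0.857) or Fear-Only animal 3 (0.534). Oligodendrocyte markers had a median of −0.99 (adjusted p = 0.0168; adjusted p = 0.460 with an estimated correlation), lost without Context-Only animal 3 (adjusted p = 0.365) or Fear-Only animal 2 (0.926). Endothelial markers had a median of 3.54 with 6 of 7 above 0 (adjusted p = 0.0462; adjusted p = 0.460 with an estimated correlation), which turned to −0.76 without Fear-Only animal 3 (adjusted p = 0.424) and was lost without Context-Only animal 2 (0.115), 3 (0.204) or 4 (0.189) or Fear-Recall animal 3 (0.0506) and with the set as a block (0.0612). Genes of oxidative phosphorylation had a median of −0.47 with 70 of 75 below 0 (adjusted p = 0.00369; adjusted p = 0.833 with an estimated correlation), which turned to 0.35 without Context-Only animal 2 (adjusted p = 0.000102) and was lost without Fear-Only animal 3 (0.648) and without the low-gene clusters (0.156). Without Fear-Only animal 2 or 3 a lone animal stands for that arm, under the same assumption about its spread. None of 20381 genes passed in edgeR (smallest adjusted p 1), 514 had an unadjusted p under 0.05, limma-trend passed 0 and DESeq2 18, Hddc3, Eno1b, Sstr5, Dll4 and Selplg among them. In edgeR 2 passed without Context-Only animal 2, Eno1b among them (adjusted p = 0.000102).

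Over all gates, Fear-Recall and Context-Only were compared with 5 animals each. Cells with a reporter read made up 62.3% of Fear-Recall and 45.8% of Context-Only cells, and inhibitory neurons 29.9% and 35.9%. Sfxn1, a mitochondrial serine transporter, was at 102 ± 13.4 CPM in Fear-Recall and 162 ± 30.4 in Context-Only (log2 fold change −0.67, SE 0.17). Zfp688 was at 16.6 ± 1.86 against 32.7 ± 12.7 CPM (−0.98, SE 0.26) and Gpatch11 at 29.2 ± 1.84 against 44.2 ± 6.55 CPM (−0.60, SE 0.18). Irs4, an insulin receptor substrate, held 475 counts against 0, at least 154.1-fold higher. This was a low level in Fear-Recall sums of 93026479 to 389855997 counts, reporter included. Haus6 had a log2 fold change of 1.78 (SE 0.53). Proteasome genes had a median of −0.43 with 28 of 31 below 0 (adjusted p = 1.9e-12; adjusted p = 0.552 with an estimated correlation), with Psmd4 at −0.56 (SE 0.20). Genes of oxidative phosphorylation had a median of −0.53 with 72 of 75 below 0 (adjusted p = 1.9e-12; adjusted p = 0.916 with an estimated correlation). Ribosomal protein genes had a median of −0.42 with 83 of 85 below 0 (adjusted p = 5.4e-10; adjusted p = 0.916 with an estimated correlation), the latter lost without Context-Only animal 2 (median −0.02, adjusted p = 0.644). Oligodendrocyte markers had a median of −0.86 with 9 of 10 below 0 (adjusted p = 0.00564; adjusted p = 0.634 with an estimated correlation), with Mobp at 9.31 against 21.5 CPM. Their call was lost with the set as a block (adjusted p = 0.114) and without Context-Only animal 3 (0.137) or Fear-Recall animal 1 (0.0515). The immediate early list did not pass (median 0.14, adjusted p = 0.700). Within sets 2, 3, 4 and 5 its score in Fear-Recall was above that in Context-Only, by 0.29, 0.14, 0.92 and 0.19, and the ribosomal score differed by −0.60, −0.16, −0.16 and −0.15 (not tested), with the 2 Context-Only animals of set 5 averaged. Scores of oxidative phosphorylation and the proteasome were below those of Context-Only in 4 of 4 sets as well, and that of the excitatory markers above (mean 0.33, SD 0.15). None of 19698 genes passed in edgeR (smallest adjusted p 0.9999), 702 had an unadjusted p under 0.05 with 985 expected by chance, DESeq2 passed 6 and limma-trend 0. The expected count leaves out the pairing by set. In 8 other splits that also parted every same-number pair, at most 290 genes were under 0.05. These splits are too few for a share under 0.05, so they cannot decide on chance.

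Fear-Recall against Homecage compared 5 with 4 animals over all gates, since a Homecage animal with a single cell was not used. Sfxn1 was again on the lower side, at 102 ± 13.4 against 192 ± 7.79 CPM (log2 fold change −0.92, SE 0.18), as were Zfp688 at 16.6 against 42.5 CPM (−1.36, SE 0.28). So was the synaptic adhesion gene Nrxn3 at 262 ± 82.1 against 551 ± 170 CPM (−1.07, SE 0.25). Ggcx was at 15.8 ± 2.82 against 3.95 ± 0.613 CPM (2.00, SE 0.43) and the integrator subunit Ints8 at 16.2 against 5.51 CPM (1.55, SE 0.37). Ribosomal protein genes had a median of −0.59 with 84 of 85 below 0 (adjusted p = 5.8e-24; adjusted p = 0.705 with an estimated correlation). The median was −0.67 for genes of oxidative phosphorylation with 71 of 75 below 0 (adjusted p = 5.8e-22; adjusted p = 0.705 with an estimated correlation) and −0.37 for genes of the proteasome with 27 of 31 below 0 (adjusted p = 1.6e-08; adjusted p = 0.705 with an estimated correlation). Genes encoded by the mitochondrion had a median of −0.36 with 12 of 13 below 0 (adjusted p = 0.0203; adjusted p = 0.955 with an estimated correlation), lost without Fear-Recall animal 1 (adjusted p = 0.102) or 4 (0.0896) or Homecage animal 2 (0.508), and without the low-gene clusters (0.0502). Cells of the low-gene clusters made up 15.9% of Homecage and 3.73% of Fear-Recall cells, and the median number of genes per cell was 5626 and 7168.5. In Homecage animal 2, 56.5% of pos cells belonged to those clusters. None of 19698 genes passed in edgeR (smallest adjusted p 0.558), 1745 had an unadjusted p under 0.05 with 985 expected by chance, limma-trend passed 0 and DESeq2 87, the 5 genes named here among them. In 6 other splits that also parted every same-number pair, at most 1574 genes were under 0.05. These splits are too few for a share under 0.05, so they cannot decide on chance. Sfxn1 lies on chromosome 13 from 54071869 to 54108342, Ggcx on chromosome 6 from 72414308 to 72430712 and Nrxn3 on chromosome 12 from 88722876 to 90334935.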

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

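Chosen only after the result was seen were the tests of the inhibitory share behind the immediate early list, of low-gene clusters behind the ribosomal list, of both neuron classes behind the gate genes, and the matched scale of the deep-cell test; the others were written first.

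Lmo3 stood apart in a single animal. On log2(CPM + 1) by library total, without TMM scaling, its pos minus neg difference was 0.023 in Fear-Only animal 2, while the other 7 animals lay between −0.69 and −1.15. With TMM-scaled CPM it was lower in pos neurons in all 8 animals. Of 54 groups of values tested in this way 1 stood out, and chance alone picks about 1 in 20 groups, or 2.7.

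The deep-layer excitatory list differed in its gate difference between Fear-Recall and the other conditions, with an adjusted p of 0.0363 by camera on the interaction (adjusted p = 0.617 with an estimated correlation), and no gene of the list passed.

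Cells of no given gate and those of the plate marked with both gates held reporter reads in larger shares than the neg gate, whose highest share was 12.8%. The share was 51.0% (95% interval 40.6 to 61.4) on the Homecage animal 3 plate marked with both gates (96 cells). Among cells of no given gate it was 28.6% (20.2 to 38.2) in Context-Only animal 5, 30.7% (23.4 to 38.7) in Context-Only 5b, 100% (from 90.3) in Fear-Only 1, 28.3% (20.9 to 36.5) in Fear-Only 5, 57.7% (50.03 to 65.1) in Fear-Recall 1, 40.9% (31.6 to 50.7) in Fear-Recall 5 and 38.8% (30.5 to 47.6) in Homecage 5. No gate was assigned to these cells from their values.

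The immediate early list was higher in pos than in neg neurons, with a median log2 fold change of 0.50. Within excitatory neurons alone it was 0.51 (fry p = 0.00188), and without the low-gene clusters 0.54 (fry p = 0.000391), which argues against a larger share of inhibitory neurons and against low-gene cells as the whole cause. With each cell weighing the same the median was 0.15, which met the bound written before for deep cells weighing more in the sums (under 0.5 of the fitted 0.495), but that bound set fitted fold changes against log2(CPM + 1). On the same scale, matched afterwards, the sums gave 0.24 and cells of equal weight 0.15, with means over animals of 0.30 and 0.27, so an effect of the list and one of deep cells cannot be told apart from these values. Activity at labelling, which the gate stands for, may lie behind the difference as an untested explanation.

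The ribosomal protein list was lower in Fear-Recall than in Context-Only pos neurons, with a median of −0.62. Without Context-Only animal 2 the median was 0.075, so the fitted difference over all sums may rest on that animal, although within sets 3 and 4 the score also differed by −0.19 and −0.13. Without the low-gene clusters the mean within-set difference was −0.25 (SD 0.17), against −0.29 (SD 0.24) with them, and an effect of these cells on the remainder cannot be told apart from none with 3 sets. A difference between conditions gave an exact two-sided sign-flip p of 0.25, the smallest that 3 sets allow, and stays open.

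The genes that passed between pos and neg neurons had a median fitted log2 fold change of 1.26 in their direction. Within excitatory neurons it was 0.55 (43.5% of that; 42 of the 51 genes in the fit, 8 of them opposite) and within inhibitory neurons 0.66 (52% of that; 50 genes, 1 opposite). Per animal the values were 1.08 (SE 0.06) over all neurons, 0.24 (SE 0.08; 22.3%) within excitatory neurons, with 17 of 51 opposite, and 0.48 (SE 0.04; 44.7%) within inhibitory neurons of 7 animals, with 2 opposite. The larger share of inhibitory neurons (40.8% of pos against 21.7% of neg cells) may account for part of the difference. The size of that part cannot be told from these values, since the fitted ones lie between the bounds and the 2 ways of averaging differ. The 51 genes were also picked by their values over all neurons, which by itself can make values within a class smaller.

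Other splits of the same animals were fitted in the same way. For the gate, 60 of the 128 ways of exchanging gate names within animals were fitted, the real one included. Only the real one gave as many genes (51 genes, highest other 0). This share of 1 in 60 is the smallest that these splits allow. Exchanging gate names also exchanged plates, except in Context-Only animal 4, so these splits cannot separate gate from plate. At an unadjusted p under 0.05 the real one had 1880 genes and the highest other 1719. In the all-gate comparisons the real count was 0, which any split equals or exceeds, so the 60 of 60 splits drawn from 126 (highest other 0 for Context-Only and 1 for Homecage) say nothing about chance. For pos, pos excitatory and pos inhibitory neurons, 10 of 10 splits gave as many as the real 0 (highest other 0 in each), and 10 splits are too few for a share under 0.05. Some splits called many genes at an unadjusted p under 0.05, which points to a structure of the samples beside condition. The real counts were 688 (highest other 3145) in pos, 772 (2326) in pos excitatory and 726 (2421) in pos inhibitory neurons, and 702 (2519) and 1745 (2839) over all gates. Among splits parting as many same-number pairs as the real one the highest were 432, 487, 688, 290 and 1574. Those splits were too few in each comparison for a share under 0.05.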

How the results depend on the processing

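Leaving out the low-gene clusters, testing genes of a mean CPM of 10 or more, fitting each neuron class of the gate comparison, thinning reads and all list results under alternatives of the fit were chosen after the data were seen. So was leaving out each animal for the inhibitory and reporter shares. Unless said otherwise the cause of a change was not tested. Of 4709 values of single genes under alternatives, 4481 kept their direction and side of the threshold, 131 fell short of it, 68 came to pass and 29 reversed. Only the gate comparison over all neurons had genes past the threshold in its main fit, so all 131 came from it. Elsewhere a gene kept its side by not passing again, so the total does not measure how stable the calls were. Of 954 list values, 728 kept both, 12 reversed and the others fell short. Here the direction of a list is that of camera, which sets the list against the other genes. A median can therefore keep its sign in a list counted as reversed, or turn in one that was not. The planned comparisons of 5 glial and vascular cell types, with their alternatives, were not run. The self-test limits what a pos comparison of 3 animals could show, with 1% of 2-fold changes recovered by edgeR.

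Counts of genes moved with the tool. DESeq2 passed 24 (pos Fear-Recall against Context-Only), 7 (Fear-Recall against Fear-Only), 18 (Fear-Only against Context-Only), 27 (pos excitatory), 38 (pos inhibitory), 6 and 87 (all gates, against Context-Only and Homecage), where edgeR passed 0 and had 688, 384, 514, 772, 726, 702 and 1745 at an unadjusted p under 0.05 and limma-trend passed 0. DESeq2 passed 647 for the gate and 2 for its interaction, but also made 126 false of 320 calls in the self-test of the gate. For the gate limma-trend passed 90, the fit without the replicate block 21, without the low-gene clusters 28, genes of a mean CPM of 10 or more 145, excitatory neurons only 6 and inhibitory neurons only 0 (1111 at an unadjusted p under 0.05 in edgeR). For the 145 fewer genes were tested and the fit was estimated anew on them, and the cause of the rise was not tested.

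With an estimated correlation the lists past the threshold went from 8, 4, 7, 7, 6, 4 and 4 in the 7 condition comparisons to 0 in each, from 11 to 1 for the gate and from 1 to 0 for its interaction. With the replicate block and an estimated correlation it was 0 in all 7, and 2 and 0 for the gate and its interaction without the replicate block and with an estimated correlation. The interaction had 0 lists without the block, 3 with no filter and 4 with per-cell means. Fear-Recall against Fear-Only had 7 with no filter, 7 with per-cell means and 8 without the low-gene clusters; Fear-Only against Context-Only 4 with per-cell means and 0 over genes of a mean CPM of 10 or more; pos Fear-Recall against Context-Only 4 with cells of no given gate; pos excitatory neurons 11 without the low-gene clusters; the gate 7 over genes of a mean CPM of 10 or more and 6 in excitatory neurons only.

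With the set as a replicate block, the oxidative phosphorylation list of Fear-Recall against Fear-Only turned from a median of −0.20 to 0.09 (adjusted p = 0.575; 0.898 with the block and an estimated correlation), its ribosomal list lost its call (0.365), and in Fear-Only against Context-Only the endothelial (0.0612) and synaptic vesicle (0.222) lists did so. In Fear-Recall against Context-Only the block ended the calls of the deep-layer list in pos neurons (0.141) and of the oligodendrocyte list over all gates (0.114), and the block ended no other list call of a condition comparison.

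With cells of no given gate added, the deep-layer list of pos Fear-Recall against Context-Only reversed (adjusted p = 0.838, median 0.12), as did Sulf1 (0.07). In Fear-Only against Context-Only Sstr5 (−0.13), Ctss (−0.12), Dll4 (−1.75), Magee1 (0.024) and Cadps2 (0.23) reversed, in pos excitatory neurons Cachd1 (−0.58), Nnat (0.30) and Fezf2 (0.10), and in pos inhibitory neurons Gpr37l1 (−1.36) and Ctss (−1.04). For the gate in excitatory neurons only, the glutamate receptor list (camera adjusted p = 0.774) and the excitatory markers (0.844) reversed in camera's direction. Their medians of −0.019 and −0.078 shrank but stayed below 0. The genes Npy (−0.93), Cd63 (−0.59), Pthlh (−0.44), Igf1 (−2.31), Adarb2 (−1.57), Fezf2 (0.018), Neurod6 (0.004) and Aldoc (−0.14) reversed there too. In inhibitory neurons only, Meis2 (4.30) and Aldoc (−0.084) reversed. Genes encoded by the mitochondrion reversed there in camera's direction (adjusted p = 0.967), while their median of 0.065 stayed above 0.

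Where leaving out an animal left 1 in an arm (Fear-Only in pos neurons, Fear-Recall in the interaction), that animal was assumed to vary like the other groups. Leaving out each animal in turn, the gate count ranged from 1 (without Fear-Recall 2) to 32 (without Context-Only 2), and was 5 without Fear-Recall 3, 6 without Fear-Only 3, 26 without Fear-Only 2, 27 without Context-Only 3, 30 without Context-Only 4 and 31 without Homecage 2. The counts of Fear-Recall against Fear-Only and of Fear-Only against Context-Only ranged from 0 to 2, with 2 without Context-Only 2, and the other condition counts and the interaction stayed at 0 by edgeR. List counts ranged from 6 to 9 in pos Fear-Recall against Context-Only, 2 to 9 against Fear-Only (9 without Context-Only 2, 8 without Fear-Recall 2, 2 without Fear-Recall 4), 5 to 8 in Fear-Only against Context-Only, 4 to 11 in pos excitatory (11 without Context-Only 2, 4 without Context-Only 4) and 2 to 8 in pos inhibitory neurons (2 without Context-Only 2), 3 to 5 and 3 to 7 over all gates (7 without Homecage 4), 9 to 13 for the gate and 0 to 5 for its interaction (0 without Context-Only 2, 3 or 4, 2 without Fear-Only 2 or 3, 4 without Homecage 2, 5 without Fear-Recall 2 or 3).

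Reversals with an animal left out gave these ranges of adjusted p: in pos Fear-Recall against Context-Only 1.1e-18 to 0.972 for oxidative phosphorylation and 7.7e-26 to 0.972 for ribosomal genes, in Fear-Recall against Fear-Only 4.5e-08 to 0.882 and in Fear-Only against Context-Only 5.0e-13 to 0.648 for oxidative phosphorylation, and in pos inhibitory neurons 9.8e-17 to 0.0841 for oxidative phosphorylation and 2.2e-21 to 0.165 for ribosomal genes. Log2 fold changes ranged in Fear-Only against Context-Only from −1.25 to 0.19 for Ndufb8, −1.04 to 0.11 for Ndufs7, −1.43 to 0.29 for Ndufa12, −0.96 to 0.087 for Psmb6, −1.14 to 0.23 for Psmb2, −0.98 to 0.27 for Psma7 and −2.76 to 8.84 for Cldn5, and in pos inhibitory neurons from −1.65 to 0.18 for Rpl34. The inhibitory share differed by −10.4 to −3.29 points between Fear-Recall and Context-Only and by 18.3 to 19.8 between gates, and the reporter share by 55.0 to 64.9. Leiden resolution 0.5 gave −5.73 and 18.8 points.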

Other observations

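All tests of this part other than the camera tests over all neurons were chosen after the data were seen. Several inhibitory clusters carried the genes of known interneuron classes. Cluster 1 (306 cells) was led by Crispld2, Penk, Calb2 and Vip, cluster 5 by Car4, Zbtb20, Igf1, Crh and Vip, and cluster 8 by Sncg, Cnr1 and the serotonin receptor gene Htr3a. Cluster 12 (130 cells) was led by Sst, Lypd6 and Cort, cluster 14 (120 cells) by Ndnf, Cplx3 and Reln, cluster 18 (51 cells) by Pvalb, Lhx6 and Cox6a2, and cluster 19 (27 cells) by Crhbp, Nos1, Sst, Npy and Chodl. Among excitatory clusters, cluster 2 was led by Cux2 and Rorb, genes of upper layers, cluster 4 by Sla, Foxp2 and Syt6, and cluster 6 (231 cells) by Myl4, Tshz2 and Slc17a6. Sets divided some excitatory clusters. Cluster 2 held 2 cells in each of sets 1, 4 and 5 and cluster 0 held 4, 3 and 10 there, with all others in sets 2 and 3. Cluster 3 held 3 and 1 cells in sets 2 and 3 and cluster 4 held 11 and 14, with all others in sets 1, 4 and 5.

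Mean scores of 34 lists were compared between pos and neg neurons of 8 animals, without adjustment over lists (exact two-sided sign-flip test, smallest p 0.0078). Genes of CREB-dependent plasticity were lower in pos neurons in 8 of 8 animals (mean difference −0.22, SD 0.14, p = 0.0078), as were genes of rab membrane traffic (−0.21, SD 0.20, p = 0.0078). Genes of activated microglia were higher in 8 of 8 animals (0.11, SD 0.07, p = 0.0078). None of the 3 lists passed camera (adjusted p = 0.0766, 0.0709 and 0.0962). With each cell weighing the same they differed by −0.20 (lower in 8 of 8, p = 0.0078), −0.19 (lower in 7 of 8, p = 0.0469) and 0.08 (higher in 8 of 8, p = 0.0078). Within excitatory neurons the differences were −0.10 (lower in 5 of 8 animals, p = 0.0859), −0.16 (lower in 6 of 8, p = 0.0469) and 0.01 (higher in 4 of 8, p = 0.836). Within inhibitory neurons they were −0.22 (lower in 6 of 7 animals, p = 0.0469), −0.16 (lower in 5 of 7, p = 0.156) and 0.22 (higher in 7 of 7, p = 0.0156).

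Clusters 10 and 11 had the fewest genes per cell, with medians of 2475.5 and 4769. They made up 57.9% of pos cells of Context-Only animal 2, 56.5% of pos cells of Homecage animal 2, 40.3% of neg cells of Fear-Only animal 2 and 35.3% of neg cells of Context-Only animal 2, and 12.8% and 8.70% of pos cells of Fear-Recall and Fear-Only animal 2. Cluster 17, led by Nrep and Tmem215, held 58 cells, of which 32 came from a single pos plate of Fear-Recall animal 2.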
